A study of Mus musculus with 12 samples.

How the data were processed

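The samples were mouse limb buds collected at E12.5. One group carried a conditional knockout of Mettl14 (both alleles floxed, called cKO), and the control group carried 1 floxed and 1 wild-type allele (called cHet). Mettl14 encodes a subunit of the enzyme complex that writes N6-methyladenosine (m6A) into RNA. Total RNA was extracted with TRIzol and made into libraries with an NEBNext Ultra II RNA kit, per the labels' protocols. A part of each RNA was sequenced directly as input, and the rest was immunoprecipitated with an antibody against m6A and sequenced as IP. Each genotype had 3 biological replicates of input and 3 of IP, which gives 12 libraries in 4 groups. The labels call the replicates biological, and do not say whether 1 replicate pooled several embryos.

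Reads were handled with fastp and HISAT2 and the genome build was mm10, per the submitters' processing notes. The program that computed expression values, its annotation, its treatment of strand and the peak caller are not given in the sources used here. The authors deposited FPKM values (fragments scaled to transcript length and library total) for 31723 genes in the 6 input libraries, per the file headers. The authors also deposited 1 list of m6A peaks per genotype, in which each peak carries a log2 fold enrichment of IP over input, per the file headers. Each peak in the authors' lists also carries a p-value and its adjusted value, per the file headers. With 1 list per genotype there is no replicate of a list, and how the replicates were combined and how IP and input were scaled to each other is not given in the sources used here. Values per library of the 6 IP samples were not used here, so the planned tests of IP over input per gene, and a joint fit of input and IP libraries, were not run. The planned search for the m6A sequence motif in peaks needs a genome sequence and was not run. All 6 columns of per-sample values were matched to a sample, so that 0 were left out. Peak positions are given on mm10, 1-based, as the authors' lists give them after adding 1 to the start. Of the gene symbols in the expression table, 25383 were found in a RefSeq gene table of assembly GRCm38.p6, and 63 symbols stood on more than 1 row. Genes are named by the symbols that the authors' table pairs with Ensembl identifiers.

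The deposited FPKM columns summed to 261691.5 to 275299.5 in cHet and 237287.9 to 255907.3 in cKO, so the genotypes did not overlap. Genes listed at 0 numbered 5671 to 5874 in cHet and 6252 to 6822 in cKO. In each library 13337 to 13622 genes had at least 1 FPKM. Total counts are not part of the FPKM table. Low values times gene length recurred at a common step in each library, which would equal 35.9 to 40.7 M fragments per library if the step is 1 fragment. The step was searched only within a set window, which bounded the possible depth in advance. Only 2.09% to 4.4% of the low values lay on that step, against 0.391% to 0.459% on a step of median occupancy, so this depth is a rough estimate and no count test was run. Correlations of log2(FPKM + 1) across genes, which are not independent of each other, were 0.976 to 0.989 within a genotype and 0.950 to 0.971 between genotypes.

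Input RNA of cKO was compared with cHet by limma (lmFit and eBayes with a trend in the prior variance) on log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 input libraries were tested, and Benjamini-Hochberg adjusted p under 0.05 was called. Log2 changes are therefore on the log2(FPKM + 1) scale, which understates the change of low genes. Folds given without log2 are ratios of mean FPKM. SDs are over the 3 replicates of a genotype. All adjusted p-values for genes come from limma, two-sided.

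Before the data were examined, 25 gene lists with 426 genes were fixed from general knowledge, of which 423 genes were found in the table. The lists were m6A writers, m6A readers and erasers, cartilage matrix and chondrocyte differentiation, hypertrophic and osteoblast differentiation, joint interzone, BMP pathway, RUNX factors, matrix proteases and inhibitors, connective tissue matrix, limb patterning, Wnt targets, tendon, skeletal muscle, endothelium, erythroid, macrophage and leukocyte, epidermis, Schwann and neural crest, p53 targets, proliferation, interferon response, immediate early and heat shock, hypoxia and glycolysis, mitochondrially encoded, and sex chromosome genes. A few genes stand on more than 1 list (Gdf5, Nog, Runx2 and Col14a1 among them). Each list was tested against all other tested genes with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists. Camera with the correlation estimated per list, and fry, were run beside it. Fry asks whether the members of a list move, on balance, one way, without comparing them with other genes.

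The rule for named genes was also fixed before the data were examined. It took Mettl14, the 10 largest rises and the 10 largest falls among called genes whose 3 cKO values all lay beyond all 3 cHet values, and up to 4 members of each list with the smallest p. It always took Gdf5, Runx1, Runx2, Runx3, Mmp3, Mmp13, Mmp9, Mmp2, Mmp14, Col2a1, Acan and Sox9. For peaks it took the 5 peaks of each genotype with the largest enrichment that overlapped no peak of the other list, in genes with a mean of at least 5 FPKM, and the peaks on Gdf5, the RUNX genes and Mettl14. Other genes named from the lists illustrate a count and were picked after their values were seen.

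Peaks of the 2 lists were called shared where they overlapped by at least 1 bp on the same strand and chromosome. Shares carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Peak spans are genomic and include introns. Tested genes were split by whether they carried a peak in cHet only, in both lists, in cKO only or in neither, and each class was tested with camera as above. Genes with a cHet peak of at least 4-fold enrichment formed a further class. Intervals of correlations and median differences across genes came from 1000 bootstrap draws of genes. Terms of the Gene Ontology in the authors' expression table with 10 to 300 tested members were tested after the data were seen, with a one-sided hypergeometric test against the 9992 tested genes that have a term.

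In a simulation with the real genes and spreads, 13575 genes were tested and 50 were changed at each size. Limma called 4% of those changed by 0.25 on the log2 scale and 40% of those changed by 0.5. It called 86% of those changed by 1, 98% of those changed by 2, and 1 unchanged gene. Far fewer genes changed in the simulation than passed in the data, which makes its adjusted threshold stricter. These shares are therefore not the recovery in the data. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5 FPKM, no filter and a filter at a mean of 5 FPKM, TMM factors, quantile normalization, each replicate left out, no trend, the replicate number as a block, removal of mitochondrial and haemoglobin genes, other peak thresholds and overlaps, and classes of genes matched on FPKM. Leaving out genes on X and Y, and a covariate for the level of Y-linked genes, were chosen after seeing the data. Software was R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.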

Results

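RNA from mouse limb buds at E12.5 was profiled by m6A-seq, in which RNA fragments carrying N6-methyladenosine are enriched with an antibody and sequenced beside the unenriched input. Limb buds with a conditional knockout of Mettl14 (cKO) were compared with heterozygous controls (cHet). There were 12 libraries, 3 biological replicates each of cHet input, cHet IP, cKO input and cKO IP. Expression values covered 31723 genes in the 6 input libraries, and m6A enrichment was given as 1 peak list per genotype. Depth was roughly estimated from the spacing of low values, searched within a set window that bounds the result. It was 35.9, 37.9 and 39 M fragments for the cHet input libraries. For the cKO input libraries it was 40.7, 38 and 36.7 M fragments.

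Mettl14, the targeted gene (chromosome 3, 123368297 to 123386108, mm10), was lower in every cKO input library. Its level was 5.08, 4.54 and 4.39 FPKM in the 3 cHet libraries and 2.67, 3.07 and 2.63 FPKM in the 3 cKO libraries. The cKO mean was 59.8% of the cHet mean, and the fall of 0.58 on the log2 scale passed the test (adjusted p = 0.00289). Its catalytic partner Mettl3 fell from 6.88 ± 0.336 to 5.69 ± 0.283 FPKM (SD, n = 3; log2 change -0.24, adjusted p = 0.0275). Other subunits of the writer complex rose. Rbm15, an RNA-binding adaptor of the complex, went from 3.67 ± 0.569 to 10.6 ± 1.27 FPKM (log2 change 1.32, adjusted p = 9.36e-04). Rbm15b rose by 0.68, Cbll1 by 0.61 and Wtap by 0.47 on the log2 scale. Of the 11 tested m6A writers, 7 rose, 3 fell and 1 did not pass, with the same counts when adjusted over the list alone. As a set the writers did not pass camera (median log2 change 0.41, adjusted p = 0.0557). Among 12 readers and erasers of m6A, 4 rose, 1 fell and 7 did not pass, and 5 rose and 1 fell when adjusted over the list alone (set adjusted p = 0.0691). Ythdf2, a cytoplasmic m6A reader, rose from 19.9 ± 0.756 to 42.2 ± 0.496 FPKM (log2 change 1.05), and Ythdf1 rose 1.71-fold. Ythdc1, a nuclear reader, rose by 0.36 on the log2 scale, while Igf2bp2 fell to 82.9% of cHet. The demethylases differed in outcome, Alkbh5 having risen by 0.19 and Fto standing at 8.33 and 8.83 FPKM without passing (adjusted p = 0.501).

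The comparison of cKO with cHet input RNA asks which transcripts depend on Mettl14 during limb development, with GDF5, RUNX factors and matrix genes named in the title of the series. Cartilage matrix genes were lower in cKO limb buds. Acan, which encodes the main cartilage proteoglycan, fell from 5.76 ± 0.978 to 1.97 ± 0.594 FPKM (SD, n = 3; adjusted p = 0.00308), and Col2a1, the main cartilage collagen gene, fell from 62.1 ± 9.58 to 41.4 ± 3.4 FPKM (adjusted p = 0.0124). Of the RUNX genes, 2 fell as well. Runx2, a regulator of chondrocyte hypertrophy and bone formation, fell from 3.82 ± 0.291 to 2.15 ± 0.266 FPKM (log2 change -0.61, adjusted p = 0.00322), and Runx3 fell from 1.53 ± 0.329 to 0.491 ± 0.0794 FPKM (log2 change -0.76, adjusted p = 0.00378). Several limb patterning genes were higher, among them Msx2 and Gli3.

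Gdf5 encodes a BMP-family ligand of the joint-forming and chondrogenic mesenchyme (chromosome 2, 155941023 to 155945367). It fell from 21.8 ± 2.23 to 17.2 ± 1.56 FPKM (log2 change -0.32, SE 0.0944, adjusted p = 0.0363). This was among the weaker calls. It was lost under 9 of 17 alternative settings, in which the log2 change ran from -0.39 to -0.24 and the adjusted p from 0.0312 to 0.107. Runx1 was below the expression filter, at 0.641 ± 0.0766 FPKM in cHet and 0.702 ± 0.0464 FPKM in cKO. Sox9, the transcription factor that starts chondrogenesis, was 29.6 ± 1.43 FPKM in cHet and 24.7 ± 3.76 FPKM in cKO and did not pass (log2 change -0.26, adjusted p = 0.106). Without cKO replicate 2 its adjusted p was 0.035. Matrix metalloproteinases moved separately. Mmp2 rose from 55.2 ± 3.73 to 71 ± 4.51 FPKM (adjusted p = 0.0121), and Mmp14 stood at 22.7 and 23.8 FPKM (adjusted p = 0.554). Mmp9, not tested for its low level, had 0.735, 0.872 and 1.73 FPKM in cHet and 0.435, 0.457 and 0.438 FPKM in cKO. Mmp3 was listed at 0 in all cHet libraries and had 0.0348, 0.0224 and 0.0245 FPKM in cKO. Mmp13 was listed at 0 in 2 cHet libraries and 1 cKO library, with 0.0363 FPKM in the other cHet library and 0.0133 and 0.0203 FPKM in the other cKO libraries.

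**Figure D1:**
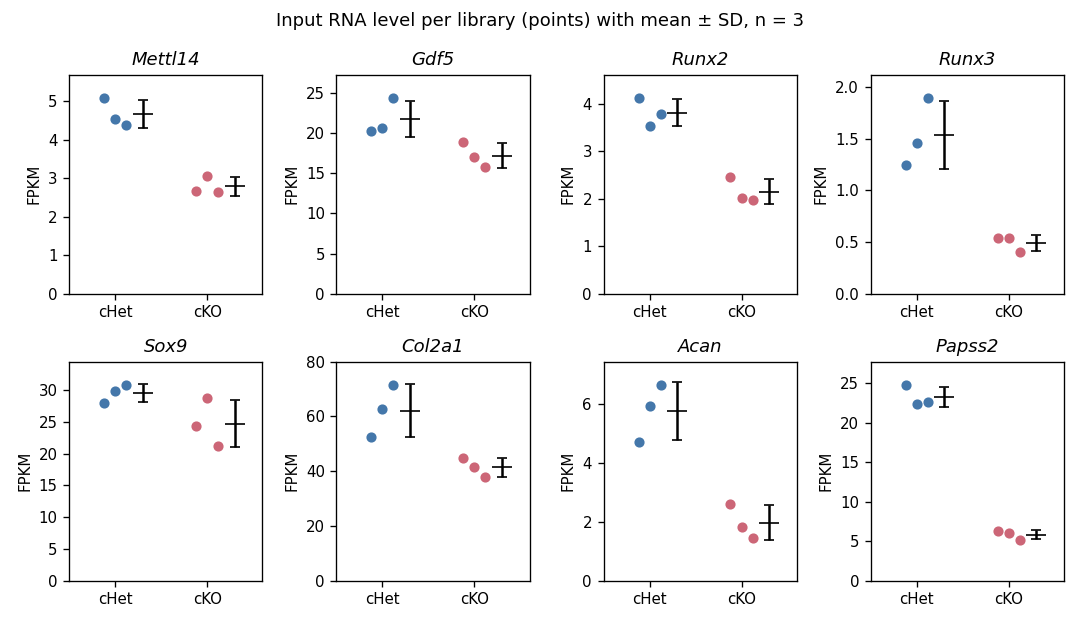
Input RNA level in FPKM (vertical axes, starting at 0) of 8 genes in the 3 cHet and 3 cKO libraries, with a point per library and the mean ± SD of each genotype beside the points. Mettl14 had 4.39 to 5.08 FPKM in cHet and 2.63 to 3.07 FPKM in cKO, Acan fell from a mean of 5.76 to 1.97 FPKM, and the Sox9 values of both genotypes overlap.

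Of 13575 genes tested, 4912 (36.2%) passed the adjusted threshold, with 2535 higher and 2377 lower in cKO, and 6420 had an unadjusted p under 0.05. Most changes were small. The median absolute log2 change of called genes was 0.41, 3309 calls were under 0.5, and 96 genes rose and 89 fell by at least 1. The 3 cKO values lay beyond all 3 cHet values for 4896 of the calls, and for 51.2% of all tested genes, against 10% by chance. Leaving out cHet replicate 2 reduced the calls to 2758 and leaving out cKO replicate 2 reduced them to 3032.

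The 10 largest falls included genes of secreted matrix proteins. Papss2, which makes the sulfate donor for proteoglycans, fell from 23.3 ± 1.31 to 5.8 ± 0.56 FPKM (log2 change -1.84, SE 0.0795, adjusted p = 3.1e-04). The secreted chondrocyte protein genes Mia and Cytl1 fell by 1.94 and dropped by 1.81 on the log2 scale. The small leucine-rich proteoglycan genes Dcn, Aspn and Kera fell to 27.7%, 25.4% and 30.5% of their cHet means. Rcn3, a calcium-binding protein of the endoplasmic reticulum, fell from 86.6 ± 8.52 to 27.5 ± 3.92 FPKM. Gm13781, an antisense gene, fell by 1.62, and Gm11966, a processed pseudogene, fell by 1.59. Both remain uncertain, since neither the use of strand nor the handling of shared reads is given. The mitochondrial tRNA gene mt-Tq had 15.6, 16.3 and 10.8 FPKM in cHet, was listed at 0 in 2 cKO libraries and had 9.74 FPKM in the other (log2 change -2.77, adjusted p = 0.0489). This was the largest fall, and its call was lost under 9 of 16 alternatives, with an adjusted p of up to 0.143.

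The largest rises were of a more mixed kind. Zfp292, a zinc finger gene, rose from 12.9 ± 3.29 to 48 ± 7.13 FPKM (log2 change 1.83, adjusted p = 0.00115), and Inka1 rose from 19.9 ± 0.755 to 63.2 ± 4.24 FPKM (log2 change 1.62, adjusted p = 3.1e-04). Exo1, a DNA repair exonuclease, rose 3.32-fold and Bcl9l, a coactivator of beta-catenin, rose 3.12-fold. Gpt, an alanine aminotransferase gene, rose from 1.64 ± 0.221 to 6.8 ± 0.637 FPKM, and Tstd1 from 1.04 ± 0.214 to 5.8 ± 0.908 FPKM. The remaining large rises are uncertain, since how reads shared between genes were counted is not given and sharing was not tested. They were the pseudogene Gm7045 (log2 change 2.03), Thoc2l, a close relative of Thoc2 (1.58), and a row of Zfp91. The first transcript type listed for this Zfp91 row was a decay transcript, as it was for Runx2, which need not describe the whole row. Zfp91 had 0.511 FPKM in cHet replicate 1, was listed at 0 in the other cHet libraries and had 1.99, 3.57 and 3.77 FPKM in cKO. Snhg4 had 0.0383, 0.872 and 0.0258 FPKM in cHet and 5.19, 1.06 and 11.1 FPKM in cKO (log2 change 2.09, adjusted p = 0.0369), and this call was lost under 9 of 16 alternatives.

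Of the 23 tested genes for cartilage matrix and chondrocyte differentiation, 18 fell, none rose and 5 did not pass, with a median log2 change of -0.83. Adjusted over the list alone, 18 fell and 1 rose, the latter being the transcription factor gene Nkx3-2 (0.36). The set passed camera (adjusted p = 6.75e-10), with adjusted p = 0.553 with an estimated correlation, and passed fry (adjusted p = 5.93e-04). Hapln1, the link protein that binds aggrecan to hyaluronan, fell from 16.3 ± 1.2 to 5.33 ± 0.129 FPKM. Col9a2 and Col9a3, subunits of collagen IX, fell to 37.8% and 37.4% of cHet, and Matn1 and Epyc fell by 1.44 and dropped by 1.55 on the log2 scale. The transcription factors of this list were not among the calls, Sox5 standing at 3.39 and 3.18 FPKM (adjusted p = 0.624) and Sox6 at 4.01 and 3.61 FPKM (adjusted p = 0.216). The median deviation of the list from its cHet level was -0.65, -0.90 and -1.04 log2 units in the 3 cKO libraries. In each cHet library it was within 0.02 of 0. Each gene was centred on its own cHet mean, so these small cHet values do not measure the spread of single genes.

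Genes of hypertrophic and osteoblast differentiation mostly had low levels, and 11 could be tested. Of these 2 rose, 5 fell and 4 did not pass (2 rose and 7 fell when adjusted over the list alone; set adjusted p = 0.0691). Panx3, a channel gene of prehypertrophic chondrocytes and osteoblasts, fell from 1.95 ± 0.512 to 0.129 ± 0.0222 FPKM, a log2 change of -1.37. Phex and Dlx6 fell by 0.93 and dropped by 0.63, whereas Pth1r, the receptor for parathyroid hormone-related protein, rose by 0.35. The untested Ihh had 1.47 ± 0.249 FPKM in cHet and 0.315 ± 0.0515 FPKM in cKO, and Ibsp had 1.36, 1.77 and 0.172 FPKM in cHet and was listed at 0 in all cKO libraries. Of 14 joint interzone genes, 1 rose, 7 fell and 6 did not pass (2 rose and 7 fell adjusted over the list alone; set adjusted p = 0.0691). Nog, a BMP antagonist, fell from 7.98 ± 0.646 to 3.89 ± 0.278 FPKM, Sulf1 fell to 59.8% of cHet and Barx1 fell to 49.7% of cHet, while Dcx rose 1.38-fold. Among 6 RUNX factors and partners, Runx2 and Runx3 fell, Runx1t1, Tle1 and Tle3 rose by 0.38, 0.28 and 0.36, and the obligate partner Cbfb stood at 52.6 and 50.5 FPKM (3 rose and 2 fell adjusted over the list alone; set adjusted p = 0.917). The median of this list was 0.11 and its mean -0.07, so the sign depends on the summary used. Of 15 matrix proteases and inhibitors, 3 rose, 5 fell and 7 did not pass (3 rose and 6 fell adjusted over the list alone; set adjusted p = 0.504). The inhibitor genes Timp1 and Timp3 fell to 47.2% and 70.1% of cHet, Adamts9 fell by 0.36, and Mmp23 rose by 0.58 on the log2 scale.

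Loose connective tissue and tendon genes were lower in cKO, least so in cKO replicate 1. The median deviation of the connective tissue list was -0.27, -0.78 and -0.61 log2 units in the cKO libraries. In the cHet libraries it was -0.16, 0.04 and 0.14. For the tendon list it was -0.37, -0.95 and -0.73 in cKO and -0.13, 0.04 and 0.12 in cHet. Of 26 connective tissue matrix genes, 15 fell, none rose and 11 did not pass, with the same counts when adjusted over the list alone (median log2 change -0.59, set adjusted p = 2.96e-04; adjusted p = 0.553 with an estimated correlation). Lum fell from 94.9 ± 9.37 to 35 ± 6.54 FPKM and Ogn from 46 ± 4.18 to 16.1 ± 4 FPKM, both small proteoglycans that bind collagen fibrils. Col1a2 fell from 56.1 ± 7.28 to 27.7 ± 3.16 FPKM, while Col1a1, at 56.1 ± 21.8 and 35.8 ± 9.12 FPKM, did not pass (adjusted p = 0.166). Fibronectin and fibrillin genes showed no detectable difference, Fn1 having 38.8 and 38.4 FPKM and Fbn2 having 23.6 and 23.5 FPKM. Of 9 tendon genes, 4 fell and 5 did not pass, and 1 rose and 7 fell adjusted over the list alone (median -0.72, set adjusted p = 0.00919; adjusted p = 0.553 with an estimated correlation). Tnmd, a tendon membrane protein gene, fell from 1.82 ± 0.674 to 0.228 ± 0.132 FPKM, Chodl fell to 29.2% and Col14a1 to 54.9% of cHet. The tendon transcription factor genes Scx (19.3 and 16.8 FPKM, adjusted p = 0.0951) and Mkx (9.92 and 8.79 FPKM, adjusted p = 0.0956) did not pass over all genes.

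Skeletal muscle genes were lower in 2 of the 3 cKO libraries. The median deviation of the list was -0.09, -0.60 and -0.58 log2 units in the cKO libraries and -0.11, -0.01 and 0.12 in the cHet libraries. Of 18 tested, 6 fell, none rose and 12 did not pass, and 10 fell adjusted over the list alone (median log2 change -0.43, set adjusted p = 0.00119; adjusted p = 0.619 with an estimated correlation), and fry did not call the list (adjusted p = 0.101). The myogenic transcription factor genes Myod1 (22 ± 2.66 to 13.5 ± 2.7 FPKM), Myf5 (3.54 ± 0.548 to 1.92 ± 0.539 FPKM) and Myog (60.8 ± 4.23 to 42.3 ± 7.3 FPKM) fell, as did the fusion gene Mymk, which fell to 61.4% of cHet. Of 15 hypoxia and glycolysis genes, 10 fell, none rose and 5 did not pass, with the same counts adjusted over the list alone (median -0.30, set adjusted p = 0.00169; adjusted p = 0.553 with an estimated correlation). The glycolytic genes Aldoa, Ldha and Tpi1 fell by 0.58, dropped by 0.52 and decreased by 0.40, and Egln3, a HIF target, fell from 3.04 ± 0.0757 to 1.84 ± 0.0696 FPKM. The 13 mitochondrially encoded genes had a median of -0.26 and passed camera (adjusted p = 0.0455; adjusted p = 0.75 with an estimated correlation). The genotypes overlapped, with median deviations of 0.14, 0.10 and -0.24 in the cHet libraries and -0.21, -0.37 and -0.09 in the cKO libraries. In this list mt-Nd5, mt-Nd6 and mt-Co3 fell and 10 did not pass, and 0 passed adjusted over the list alone.

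Patterning genes moved the other way. Of 30 limb patterning genes, 15 rose, 3 fell and 12 did not pass, with 17 rises and 3 falls adjusted over the list alone (median log2 change 0.26, set adjusted p = 6.97e-04; adjusted p = 0.553 with an estimated correlation). Msx2, a target of BMP signalling at the limb margin, rose from 10.5 ± 0.604 to 27 ± 3.15 FPKM, and Gli3, the repressor of Hedgehog targets, rose from 15.2 ± 1.04 to 30.9 ± 2.68 FPKM. Hand2 rose 1.67-fold, Hoxa9 1.63-fold and Hoxd13 from 140 ± 3.37 to 237 ± 32 FPKM. The Hedgehog target genes Gli1 and Ptch1 fell by 0.68 and dropped by 0.44 on the log2 scale, and Hoxd12 fell by 0.43. The proximal markers Meis1 (3.08 and 3.05 FPKM) and Meis2 (4.98 and 5 FPKM) did not pass. Of 12 Wnt target genes, 7 rose, 2 fell and 3 did not pass, with the same counts adjusted over the list alone (set adjusted p = 0.188). Axin2, a feedback inhibitor of Wnt signalling, rose 1.76-fold (adjusted p = 0.00346), Znrf3 rose by 0.82 and Notum by 0.46, and Lgr5 fell by 0.43. Of 26 BMP pathway genes, 4 rose, 7 fell and 15 did not pass, and 6 rose and 10 fell adjusted over the list alone (set adjusted p = 0.57). The pathway inhibitors Smad7 and Bambi rose 2.58-fold and 2.07-fold, while the secreted antagonists Nog and Fst fell to 48.8% and 52.9% of cHet. The BMP response genes Id1 (65.9 and 70.2 FPKM), Id2 (49.5 and 49.7 FPKM) and Id3 (52.1 and 58.1 FPKM) did not pass, while Id4 fell from 5.79 to 4.45 FPKM (log2 change -0.32, adjusted p = 0.0228).

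**Figure D2:**
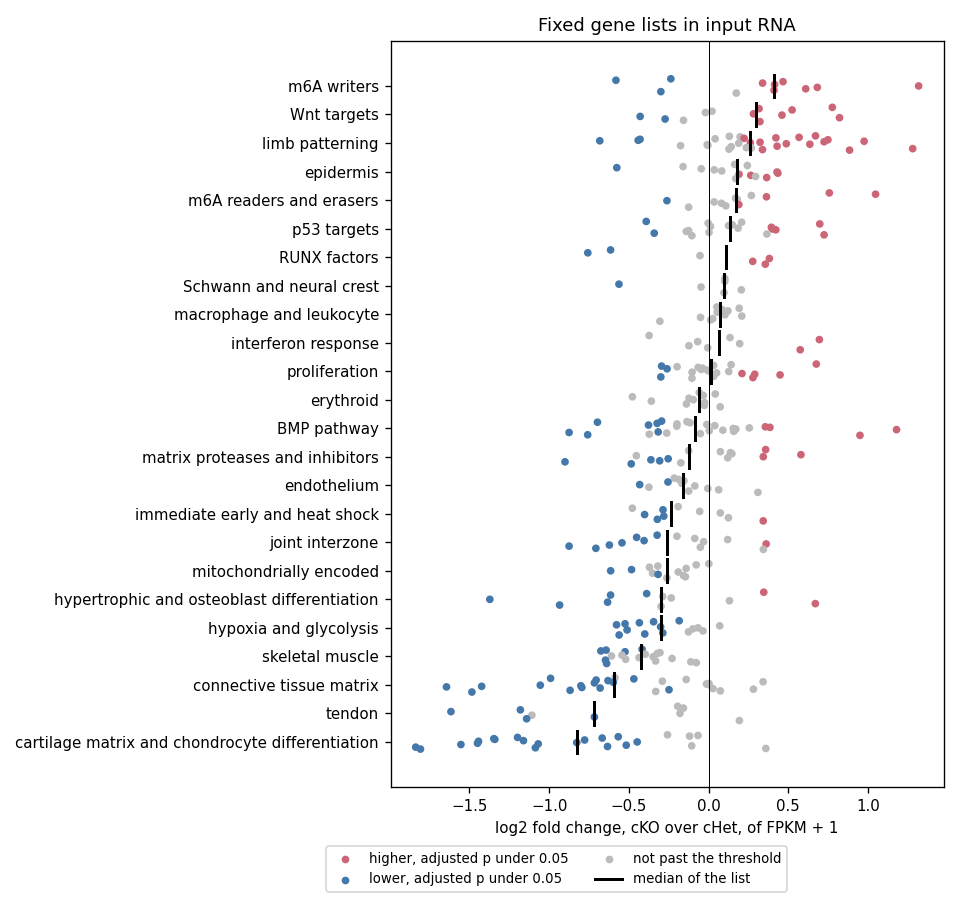
Log2 fold change of input RNA, cKO over cHet (horizontal axis, FPKM + 1), for each tested gene of 24 fixed lists (vertical axis, ordered by median), with 1 point per gene and a black bar at the median. Cartilage genes lie lowest with a median of -0.83, followed by tendon (-0.72) and connective tissue matrix (-0.59), and m6A writers lie highest (0.41); the sex chromosome list is not drawn.

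Markers of blood cells showed no detectable change. None of 11 erythroid and none of 12 macrophage and leukocyte genes passed, over all genes or adjusted over the list alone. The set medians were -0.06 (adjusted p = 0.736) and 0.07 (adjusted p = 0.596). Embryonic haemoglobin Hba-x had 1026, 1243 and 812.1 FPKM in cHet and 491.8, 755.2 and 1320 FPKM in cKO. Of 12 endothelial genes, Emcn and Tek fell to 70.4% and 80.1% of cHet and 10 did not pass, with the same counts adjusted over the list alone (set adjusted p = 0.0812). Of 14 epidermal genes, 5 rose, 1 fell and 8 did not pass, again with the same counts adjusted over the list alone (set adjusted p = 0.0868). Trp63, the regulator of epidermal identity, rose from 4.9 ± 0.214 to 6.98 ± 0.39 FPKM and Krt18 fell to 62.8% of cHet. Of 6 Schwann cell and neural crest genes, none rose, 1 fell and 5 did not pass (1 fell adjusted over the list alone; set adjusted p = 0.819). The median of that list was 0.10 and its mean -0.02.

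Proliferation and stress lists were mixed. Of 22 proliferation genes, 5 rose, 3 fell and 14 did not pass, and 5 rose and 4 fell adjusted over the list alone (set adjusted p = 0.819). Birc5 rose from 26.5 ± 0.609 to 36.6 ± 0.617 FPKM, Mki67 rose by 0.68 on the log2 scale, and Tyms and Pcna fell to 80.2% and 83.3% of cHet. Of 18 p53 target genes, 5 rose, 2 fell and 11 did not pass, with the same counts adjusted over the list alone (set adjusted p = 0.235). Ddit4l rose 1.88-fold, while Cdkn1a, the p21 gene, fell by 0.39. Of 8 interferon response genes, Irf9 and Eif2ak2 rose by 0.69 and 0.57 and 6 did not pass (2 rose adjusted over the list alone; set adjusted p = 0.504). Of 10 immediate early and heat shock genes, 1 rose, 4 fell and 5 did not pass, and 1 rose and 5 fell adjusted over the list alone (set adjusted p = 0.195). Klf4 fell to 69.4% of cHet and the chaperone gene Dnajb1 rose 1.28-fold.

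Transcripts of the sex chromosomes were not evenly spread over the libraries. Xist, expressed from the inactive X of females, had 0.0442, 0.0211 and 78.8 FPKM in the cHet libraries and 43.5, 40.6 and 81.4 FPKM in the cKO libraries. The Y-linked gene Eif2s3y had 19.3, 18 and 2.35 FPKM in cHet, 7.65 and 9.55 FPKM in cKO replicates 1 and 2, and was listed at 0 in cKO replicate 3. Replicate 3 of cHet and replicates 1 and 2 of cKO thus held both Xist and Eif2s3y, as libraries with RNA of both sexes would. None of the 5 sex chromosome genes passed, over all genes or adjusted over the list alone (set adjusted p = 0.734). The median of this list was -0.75 and its mean -0.06. With the level of Y-linked genes as a covariate, chosen after seeing the data, 3360 genes passed (1740 higher and 1620 lower).

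The preset correlation matters for the sets. With 0.01, 7 lists passed camera (cartilage, connective tissue matrix, limb patterning, skeletal muscle, hypoxia and glycolysis, tendon and mitochondrially encoded), and none passed with an estimated correlation. By fry, 6 lists moved up (m6A writers, readers and erasers, limb patterning, Wnt targets, epidermis and p53 targets) and 7 moved down.

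The peak lists ask where m6A lay in limb bud RNA of each genotype. Fold enrichments and adjusted p-values of peaks are the authors' own values. In both lists more peaks were annotated to the 3′ untranslated region than to any other region. The lengths of the regions were not taken into account, so these shares do not measure a concentration of m6A. In cHet, 36.5% (95% interval 36.1 to 37%) of the 41196 peaks were annotated to the 3′UTR and 18.9% (18.5 to 19.3%) to the stop codon. In cKO, 37.3% (36.9 to 37.7%) of the 46758 peaks were annotated to the 3′UTR and 15.2% (14.9 to 15.5%) to the stop codon. Start codon peaks made up 8.25% of the cHet list and 9.83% of the cKO list, exonic peaks 17.4% and 19.2%, and peaks on exons of noncoding RNA 9.22% and 8.48%. Intronic peaks were 4.37% and 4.82%, and 5′UTR peaks 4.96% and 4.89%. The peaks lay on 16616 genes in cHet and 16585 genes in cKO, and spanned 228 and 266 Mb with introns included. In the authors' deposited lists the median log2 enrichment was 1.87 in cHet (quartiles 1.36 and 2.68) and 1.59 in cKO (quartiles 1.19 and 2.14). Stop codon peaks had medians of 2.66 in the cHet list and 2.04 in the cKO list, and 3′UTR peaks 1.62 and 1.49. An enrichment of at least 4-fold was listed for 18608 cHet peaks (45.2%) and 14242 cKO peaks (30.5%). These are separate lists with no replicate spread, and no test was made between them, because the scaling of IP to input is not given.

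**Figure D3:**
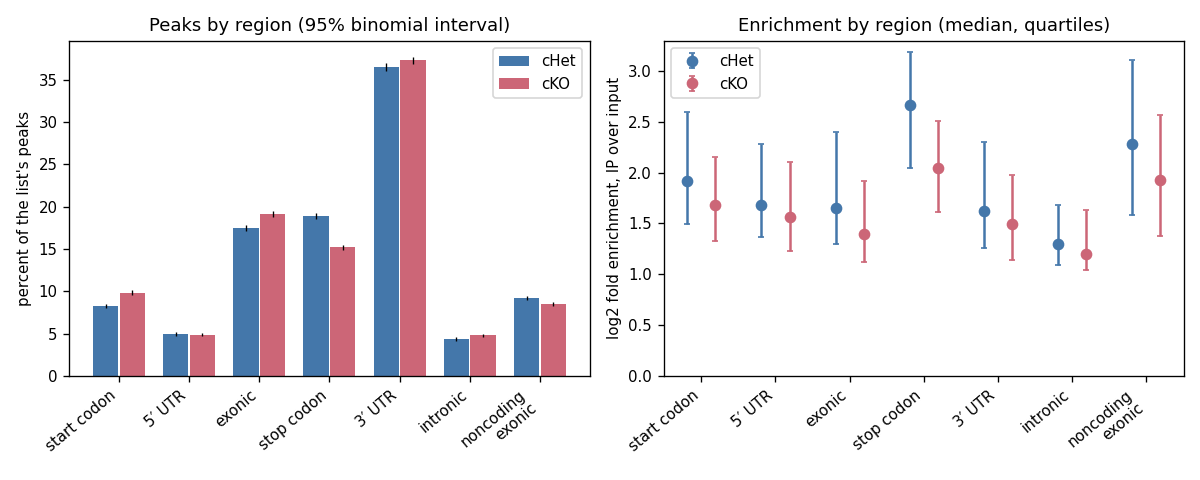
Left, percent of the peaks of each list (vertical axis, from 0) by annotated transcript region, with cHet and cKO bars and 95% exact binomial intervals. Right, median and quartiles of the authors' log2 fold enrichment of IP over input by region; stop codon peaks had a median of 2.66 in the cHet list and 2.04 in the cKO list.

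Most peaks had a counterpart in the other list. Of the cHet peaks, 35985 (87.4%, 95% interval 87 to 87.7%) overlapped a cKO peak on the same strand, and 37197 cKO peaks (79.6%, 79.2 to 79.9%) overlapped a cHet peak. This left 5211 peaks in cHet only and 9561 in cKO only. With overlap of 50% of both peaks required, the shares were 63.1% and 55.6%. The cHet peaks without a counterpart that ranked highest in the authors' deposited list were an exonic peak on Srp54b (chromosome 12, 55170957 to 55180503, log2 enrichment 4.84) and intronic peaks on Ebf2 (4.68), Robo1 (4.64) and Frmd4a (4.29). A 5′UTR peak on Ube2q2 followed with 4.21 in the authors' deposited cHet list. In the authors' deposited cKO list, high values without a counterpart were listed for an exonic peak on Gm13696 (7.62), an intronic peak on Tead3 (5.60), a 5′UTR peak on Pkp4 (4.88) and a peak on the noncoding RNA Gm5940 (4.71).

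Gdf5 carried 1 peak in the authors' deposited cHet list, spanning the gene from 155941023 to 155945367 on chromosome 2 with a log2 enrichment of 4.05 and annotated to the stop codon. The authors' deposited cKO list held 2 peaks on Gdf5, at the stop codon (155941023 to 155942222) with 2.76 and at the start codon (155942348 to 155945367) with 1.67. Runx2 had 7 peaks in cHet and 6 in cKO, and the highest enrichments in the authors' deposited lists were 3.15 for a cHet 3′UTR peak (chromosome 17, 44495987 to 44496786) and 1.89 for an exonic cKO peak. Runx3 had a stop codon peak (chromosome 4, 135175638 to 135176412) with 2.09 and a 3′UTR peak with 1.79 in the authors' deposited cHet list, and a 3′UTR peak with 1.71 in the authors' deposited cKO list. Runx1 had 6 peaks in cHet and 8 in cKO, with highest values of 3.26 and 2.35 in the authors' deposited lists. Mettl14 itself had 7 cHet peaks and 5 cKO peaks, with highest values of 2.27 and 2.01 in the authors' deposited lists.

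Whether transcripts with m6A peaks changed in level was asked by joining both data sets. Genes with strong peaks in cHet tended to be higher in cKO input RNA, and genes without a peak tended to be lower. Among the 9078 tested genes with a cHet peak of at least 4-fold, 2238 rose and 1252 fell, with a median log2 change of 0.06 against -0.14 for all other tested genes (camera p = 8.54e-10, and p = 0.0164 with an estimated correlation). This class holds most tested genes, and of all 13575 tested genes 2535 rose and 2377 fell. Msx2, Rbm15, Zfp292 and Gli3 are examples, with strongest cHet peaks of 3.70, 3.88, 3.65 and 3.18 in the authors' deposited list. The strongest peaks on the fallen genes Papss2, Cytl1 and Dcn were 1.61, 1.46 and 1.62 in the authors' deposited cHet list. Not all genes followed, since Acan and Nog fell with strongest cHet peaks of 3.54 and 3.25 in the authors' deposited list. The same holds for Gdf5 (4.05), Col2a1 (3.18) and Runx2 (3.15). Of the 10 largest falls, Kera (3.28) and Gm13781 (4.36) also carried strong peaks in the authors' deposited cHet list.

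Along the scale of enrichment, the median RNA change was -0.23 for 1476 genes without a cHet peak, -0.13 for a strongest peak of log2 enrichment 1 to 1.5 in the authors' deposited list, 0.14 for 3 to 3.5 and 0.18 for 3.5 to 4. It was 0.07 for the 157 genes at 4 or more. Of the genes at 3.5 to 4, 38.8% rose and 10.2% fell. Of the genes without a cHet peak, 5.83% rose and 19.9% fell. By region of the strongest cHet peak, the median change was 0.05 for 4743 genes at the stop codon, -0.01 for 3658 genes in the 3′UTR, 0.09 for 1107 exonic genes and -0.10 for 897 genes on noncoding exons.

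**Figure D4:**
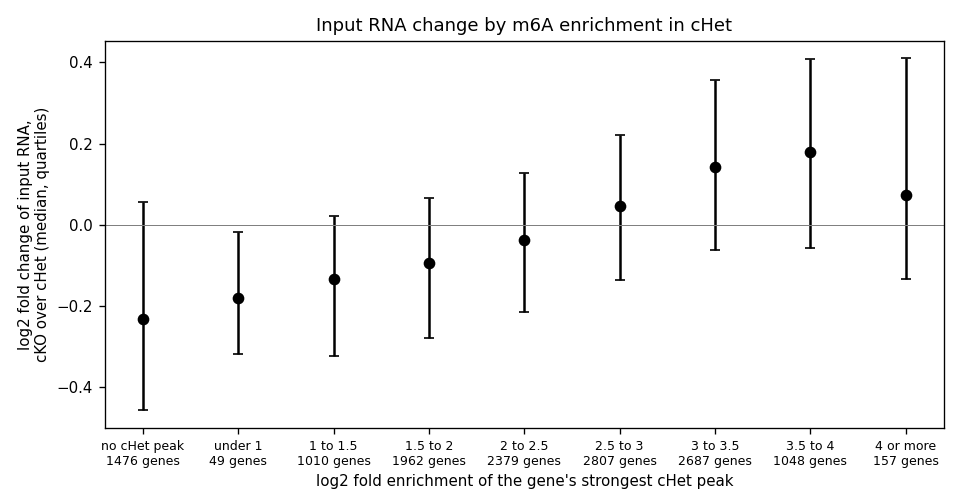
Median log2 fold change of input RNA, cKO over cHet (vertical axis, with quartiles as bars), for genes binned by the authors' log2 fold enrichment of their strongest cHet peak (horizontal axis, gene numbers under each bin). The median was -0.23 without a cHet peak and 0.18 at an enrichment of 3.5 to 4.

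At the authors' threshold for peaks, 11981 tested genes had a peak in both lists, with a median log2 change of 0.0156 (camera adjusted p = 9.34e-05; adjusted p = 0.158 with an estimated correlation). Without 1 replicate this median ran from 0.00078 to 0.0241. The 284 genes with a peak in cKO only had a median of -0.19, of which 21 rose and 88 fell. The 1192 genes with no peak had a median of -0.24 (adjusted p = 1.87e-04; adjusted p = 0.476 with an estimated correlation), which ran from -0.34 to -0.16 without 1 replicate. Fry called neither the class with peaks in both lists nor the class with none (adjusted p = 0.138 for each). The 118 genes with a peak in cHet only had a median of -0.10. For peaks of at least 4-fold, the class in cHet only held 2489 genes with a median of 0.11, opposite in sign, with 748 rises and 234 falls. The class in cKO only held 718 genes with a median of -0.14, with 46 rises and 213 falls. Input RNA is the denominator of enrichment, so a change of input RNA can itself move a gene between the classes in 1 list only, and no test of these classes is read as an effect of m6A. Peak calling depends on the RNA level of a transcript, and against genes matched on FPKM the strong-peak class, with 4497 of its 9078 genes matched, had a median of 0.04 against -0.14.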

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

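Most results kept their direction and their side of the threshold. Over the alternatives, 1839 of 1987 values for 121 named genes kept both, 135 no longer passed, 13 newly passed and 0 turned direction. For the fixed lists the counts were 418 of 470 the same, 17 weaker, 34 stronger and 1 reversed. No gene called under both the chosen and another setting changed sign. The cause of the changes below was not tested, except that fewer genes or fewer libraries were used where the setting says so.

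Leaving out 1 replicate gave 2758 to 5109 calls, with 1515 to 2606 higher and 1243 to 2503 lower. The lowest were without cHet replicate 2 (2758) and without cKO replicate 2 (3032), and without cKO replicate 3 the number higher was 1659. A filter at a mean of 5 FPKM left 1619 higher. TMM factors moved the share of calls that were higher from 51.6% to 56.9%. The mitochondrially encoded list ranged from -0.37 to -0.17 without 1 replicate and no longer passed without cHet replicate 1, cHet replicate 2 or cKO replicate 2. The tendon list ranged from -0.84 to -0.42 and did not pass without cHet replicate 3. Genes with a peak in cHet only ranged from -0.144 to -0.0503 and passed without cHet replicate 3 and without cKO replicate 3. Genes with a peak in both lists ranged from 0.00078 to 0.0241 and genes with none from -0.34 to -0.16, and both kept their calls.

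With no filter, genes with a peak in cKO only turned to 0.0026 (adjusted p = 0.509), those with a peak in both lists (0.0024) and in neither (-0.0063) no longer passed, and the RNA change of genes, peak in cHet only, passed (-0.0916). Quantile normalization turned the mitochondrially encoded list to 0.0478 (adjusted p = 0.775). With peaks of at least 4-fold only, the class in cHet only turned to 0.11 (adjusted p = 4.29e-06; adjusted p = 0.0958 with an estimated correlation), a class whose membership itself depends on input RNA, and with TMM factors it passed at -0.0834. On FPKM, 1594 of the 11981 genes with a peak in both lists could be matched. The median was 0.0156 for the whole class and -0.0036 for these genes, and the class kept its call against the matched genes, whose median was -0.22 (adjusted p = 0.00143). At a mean of 5 FPKM the tendon list (-0.18) and the mitochondrially encoded list (-0.26) did not pass, nor did the latter with Y-linked expression as a covariate (-0.25). With the correlation estimated per list, calls were lost at unchanged medians for cartilage (-0.83), connective tissue matrix (-0.59), limb patterning (0.26), tendon (-0.72), skeletal muscle (-0.43), hypoxia and glycolysis (-0.30), mitochondrially encoded (-0.26), and the peak classes in both lists (0.0156), in cKO only (-0.19) and in neither (-0.24). Fry did not call skeletal muscle (-0.43), mitochondrially encoded genes (-0.26), or the peak classes in both lists and in neither (adjusted p = 0.138 for each).

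With the replicate number as a replicate block, 2889 genes passed, 1564 higher and 1325 lower, and the mitochondrially encoded list (-0.26, adjusted p = 0.0531) was the only list or peak class to lose its call. Deviations of same-numbered cHet and cKO libraries correlated across genes at -0.08, 0.04 and -0.20, which gives no hint of pairing.

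Peaks of at least 2-fold in the authors' deposited lists had median log2 enrichments of 1.93 in cHet and 1.66 in cKO, with 19.7% and 16.1% at the stop codon and 35.6% and 36.1% in the 3′UTR. At 4-fold and a 100 times lower false discovery rate, 18608 cHet and 14242 cKO peaks remained in the authors' deposited lists, spanning 139 and 105 Mb, with medians of 2.77 and 2.46, 32.1% and 26.2% at the stop codon and 27.8% and 29.4% in the 3′UTR. The share of cHet peaks with a counterpart was 77.8% when 50% of the peak had to overlap, 63.1% for 50% of both peaks, 86.2% for 2-fold peaks, 91.8% for 4-fold cHet peaks and 92.2% in genes of at least 5 FPKM. For cKO peaks the shares were 70.3%, 55.6%, 80.4%, 93.1% and 80.7%.

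Not run were the joint fit of input and IP, the tests of IP over input with their alternatives, and the motif search. The rough depth and 3 replicates limit what small changes can be called, as 40% of simulated changes of 0.5 on the log2 scale were recovered.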

Other observations

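Beyond the fixed lists, lowered transcripts gathered in a few cell machines. Gene Ontology terms were tested after the data were seen, and 114 of 1740 terms passed for lowered genes against 4 for raised genes. Complex I of the mitochondrial respiratory chain had 31 of 44 tested members lower (7.67 by chance, adjusted p = 1.03e-11). Ndufv2, a nuclear-encoded subunit, fell from 65.7 ± 2.86 to 39.6 ± 3.12 FPKM (SD, n = 3), and Ndufb4 from 15.1 ± 0.55 to 8.94 ± 0.668 FPKM. The proteasome core had 14 of 15 members lower (2.62 by chance, adjusted p = 4.18e-08), among them Psmb6, Psma2 and Psmb2. Transport from the endoplasmic reticulum to the Golgi had 45 of 86 members lower (15 by chance, adjusted p = 5.37e-11). Sec24d, a coat protein needed to export procollagen, fell from 7.7 ± 0.369 to 4.21 ± 0.311 FPKM. Structural constituents of the ribosome had 67 of 156 lower (27.2 by chance) and collagen-containing extracellular matrix 54 of 143 (24.9 by chance). Genes in a term are not independent of each other, so these p-values are too small by an unknown amount. The FPKM sums were lower in all cKO libraries, and an effect of transcript length or scaling on these terms was not tested.

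Raised genes gathered in transcriptional control. Negative regulation of transcription had 76 of 212 members higher (43.9 by chance, adjusted p = 3.38e-04), among them Riox1 (4.88 ± 0.31 to 12.7 ± 0.96 FPKM), Klf11 (3.34 ± 0.111 to 6.87 ± 0.426 FPKM) and Sall2 (13.5 ± 0.736 to 23.3 ± 1.22 FPKM). The imprinted genes H19 and Igf2, looked at after their values were seen, fell from 2996.8 ± 49.9 to 1635.7 ± 133.5 FPKM and from 773 ± 54 to 483 ± 36.8 FPKM.

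For the number of changed genes and lists, the split by number of genes was chosen only after the result was seen, and the split by lists before. The 6 libraries can be split into 3 and 3 in 10 ways, which are too few for a share under 0.05. The real split gave 4912 calls and the highest other split 15, so that 1 of 10 splits reached the real value. For fixed lists passing camera, the real split gave 7 and the highest other 11, and 4 of 10 splits gave at least as many. The number of lists passing is therefore no larger than regrouped libraries give.

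For the RNA change of genes with strong cHet peaks, the test of sampling error of the cHet input was chosen only after the result was seen. The difference of medians was 0.199 in the real split and at most 0.111 in the others, so that 1 of 10 splits reached it, and 10 splits are too few for a share under 0.05. The cHet input enters both the RNA change and the cHet enrichment, which could link them. Across genes, which are not independent, the RNA change correlated with the cHet enrichment at 0.339 and with the cKO enrichment at 0.0196 (95% interval 0.0031 to 0.037). This lay between the bounds set beforehand and leaves shared input libraries undecided. The covariance exceeded the variance of the cHet input mean by 0.072 (0.0668 to 0.0767). This argues against sampling error of the whole-gene input level as the whole cause. The enrichment is a ratio within the strongest peak of a gene. Input error within peaks was not measured, so the test leaves it undecided. The difference went from 0.199 over all genes to 0.178 within 10 bins of expression and 0.153 within 10 bins of gene span. Each lay above a bound of 0.0664, whose rule was preset and whose value was computed from the difference over all genes. This argues against expression level and gene span as the whole cause, and a part of the difference may go with them. Gene span is genomic and includes introns, so an effect of transcript length was not tested. One hypothesis is that transcripts marked by m6A are more stable without METTL14, which RNA decay measurements might test.

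For the lower cartilage list, all 3 tests were chosen only after the result was seen. With the level of Y-linked genes in the fit the median was -0.7824 (adjusted p = 1.01e-09; range over alternatives 2.55e-13 to 0.553), which argues against the mix of female and male embryos. The proximal genes Meis1 and Meis2 changed by a mean of -0.0065 (SE 0.0925), which argues against a loss of proximal cells as the whole cause. The SE takes both genes as independent, but they moved alike across the cKO libraries, so it is likely too small. The SEs of the single genes were 0.138 and 0.123. The mean joins unlike libraries. Meis1 and Meis2 had 3.72 and 6.13 FPKM in cKO replicate 1, but lay below their cHet means in cKO replicates 2 and 3. A smaller loss of proximal cells is therefore left open. Sox9 changed by -0.258 (SE 0.108), less than the list. This argues against a lower share of SOX9-positive cells as the whole cause only if Sox9 RNA per cell was unchanged, which was not measured. Sox9 carried a strongest cHet peak of 3.21 in the authors' deposited list, and genes at 3 to 3.5 had a median RNA change of 0.14. The fall was not particular to cartilage. The tendon (-0.72), connective tissue matrix (-0.59) and skeletal muscle (-0.43) lists also had lower medians, and limb patterning had a higher one (0.26). A cause shared by these lists was not tested. For the cartilage genes alone, a slower step from SOX9-positive progenitors to matrix-producing chondrocytes is a hypothesis that may be tested in sections or single cells.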
